A study of Mus musculus with 12 samples.

How the data were processed

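Gene expression was measured in CD8 T cells of 6 male C57BL/6 mice aged 4 weeks on 12 Affymetrix HT mouse perfect-match arrays. Mice 1 to 3 were wild type, and mice 4 to 6 carried floxed Ezh2 alleles and a Cre recombinase driven by the CD4 promoter, which removes Ezh2 in T cells. Per the labels, CD8 cells were taken with antibody-coated magnetic beads from spleen and lymph nodes at a purity above 93%. Freshly isolated cells were called naive, and cells cultured for 3 days on plates coated with anti-CD3 and a costimulatory antibody were called activated. The series description names that antibody as anti-CD28 and the sample characteristics name it as anti-CD38, so its identity is taken from the description here. Each mouse gave 1 naive and 1 activated sample, which makes 4 groups of 3 arrays. About 200 ng of total RNA per sample was amplified with the Nugen Ovation Pico WTA system V2 before hybridization.

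The expression values are base-2 logarithms (log2) made by the authors with a version of RMA that uses perfect-match probes only, per the file headers; its version is not given in the sources used here. These log2 values were used as deposited. They had array medians between 0.905 and 0.976 and the same maximum of 10.595 on every array. The values in the series table and in the authors' workbook differed by at most 5.0e-09, so the series table was used throughout. No detection calls were used, and the number of arrays limits the precision. The deposited workbook also holds a ratio per comparison, the authors' fold change between group means, and ratio columns that keep a fold change only where it was selected. The authors' p_value columns come from a 2-way analysis of variance per probe set, are not adjusted, and were selected at p under 0.01 with a ratio over 1.3. The columns with the authors' pairwise p-values are recorded under the unit other, since the lines above their header hold counts, per the file headers. A plotting sheet and a worked example in the same workbook repeat probe sets of the main sheet and were not used here.

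Of 45141 probe sets, 104 control probe sets were left out. Per the annotation deposited with the values, 38544 of the others belong to 1 gene, 860 to several genes and 5633 to no gene. Each gene was represented by the probe set with the highest mean over all 12 arrays, which gave 20962 genes, of which 9714 had more than 1 probe set. Symbols were updated by gene identifier from a RefSeq gene table of assembly GRCm38.p6 for 18394 genes, and 2568 genes kept the deposited symbol. That table served for names and for the order of genes along chromosomes. The array annotation names no build, so no coordinates are given. The authors marked the chosen probe set of 897 genes as matching the antisense strand and noted possible cross-hybridization for 9753 genes. The part of Ezh2 that the floxed alleles delete is not given in the sources used here.

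The 12 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group and moderated variances (eBayes). There were 5 comparisons: activated against naive cells in each genotype, knockout against wild-type cells in each state, and the difference of the activation response between genotypes (the interaction). P-values were adjusted by the Benjamini-Hochberg method over all 20962 genes, and genes with an adjusted p under 0.05 count as passing. Tests covered both directions. Changes are log2 differences between group means with the standard error (SE) of the fit, and group values are given with the standard deviation (SD). The 31 gene lists hold 716 genes, of which 679 were measured. They cover Polycomb complexes and targets, T-cell programmes, cell growth and division, and markers of other cell types and of sample handling. Lists were tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists within each comparison, and again with an estimated correlation. The comparisons, lists, tests and the alternatives, apart from those named below as added, were fixed before the data were examined. So was the choice of genes named. That choice takes a fixed panel of T-cell genes, the 6 genes with the largest rise and the 6 with the largest fall among passing genes whose groups do not overlap, and up to 4 passing members with the largest change per list. For the interaction no test of overlap applies. Where no member of a list passed, it takes the 2 members with the largest change, and where 5 or fewer members passed in a direction, all of them. Symbols that stand for unnamed transcripts were left out of the 6 largest. Results for some of the genes so chosen are not reported here. Other tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

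The naive and activated samples of a mouse share its number. Pearson's r between their deviations from the group means, taken across genes, which are not independent replicates, was 0.04, -0.08, 0.05, 0.12, -0.04 and 0.07 for mice 1 to 6. The correlation within a mouse estimated by limma was 0.033. The model has no term for the mouse, which was fixed before these values were seen, and a replicate block for the mouse is an alternative.

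The method was tested on simulated data with 20962 genes and the same groups. In each comparison 67 genes were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. In the real activation comparisons 5612 and 5595 genes passed, so adjustment is less strict there and the shares found may differ. Changes of 2 on the log2 scale were found in 100.0% of changed genes in every comparison. Changes of 1 were found in 92.5% for both activation comparisons, 97.0% for both genotype comparisons and 86.6% for the interaction. For changes of 0.5 these shares were 55.2% and 59.7% for activation of wild-type and knockout cells, 62.7% for both genotype comparisons and 16.4% for the interaction. Between 3.4% and 6.5% of the calls fell on unchanged genes. In a simulation of 31 lists of 25 genes, the 1 shifted list was called and 0 of the unshifted lists were called by camera. The simulated genes varied independently of each other. The simulation therefore does not test false calls for lists whose members vary together, such as interferon-stimulated genes (estimated correlation 0.209).

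The alternatives were testing every probe set, the mean over the probe sets of a gene, a filter on dim genes that left 12173, a second quantile normalization, and a fit of only the arrays compared. Others were a replicate block, an intensity trend with robust variances, array weights, an unmoderated model, an adjusted p under 0.01, a change of at least 2-fold, and leaving out each array in turn. For the lists, camera with an estimated correlation and fry were run. Leaving out probe sets marked as antisense and a term for the arrays numbered 9 to 12 were added after seeing the data.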

Results

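Expression was measured on 12 arrays of mouse CD8 T cells, with 3 arrays each of naive wild-type, naive knockout, activated wild-type and activated knockout cells. The values are log2 expression estimates with array medians from 0.905 to 0.976, and the number of arrays limits their precision. Since the median probe set lies near the floor of the scale, folds for genes that are dim in 1 group are compressed. The study asked how losing Ezh2, the enzyme of Polycomb repressive complex 2 (PRC2) that methylates histone H3 on lysine 27, changes gene expression in resting and stimulated CD8 T cells. Changes are log2 differences ± SE from limma with n = 3 arrays per group, and p-values are adjusted over all 20962 genes.

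Ezh2 was measured by 1 probe set, 1416544. In naive cells of wild-type mice 1, 2 and 3 it read 2.31, 2.16 and 2.42, and in naive cells of knockout mice 4, 5 and 6 it read 1.95, 2.14 and 2.18. In activated cells it read 5.56, 5.26 and 5.35 in the wild type and 2.72, 3.59 and 3.78 in the knockout. Ezh2 was lower in activated knockout than in activated wild-type cells by -2.02 ± 0.20, a 4.07-fold difference (adjusted p = 4.09e-05). In naive cells the change was -0.20 ± 0.20 and did not pass (adjusted p = 0.845). Ezh2 rose upon activation by 3.09 ± 0.20 in wild-type cells and by 1.27 ± 0.20 in knockout cells, and the difference between these responses was -1.82 ± 0.28 (adjusted p = 0.00371). Whether the probe set lies in the deleted part of the gene is not known, so the signal left in knockout cells does not measure how complete the deletion was.

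**Figure D1:**
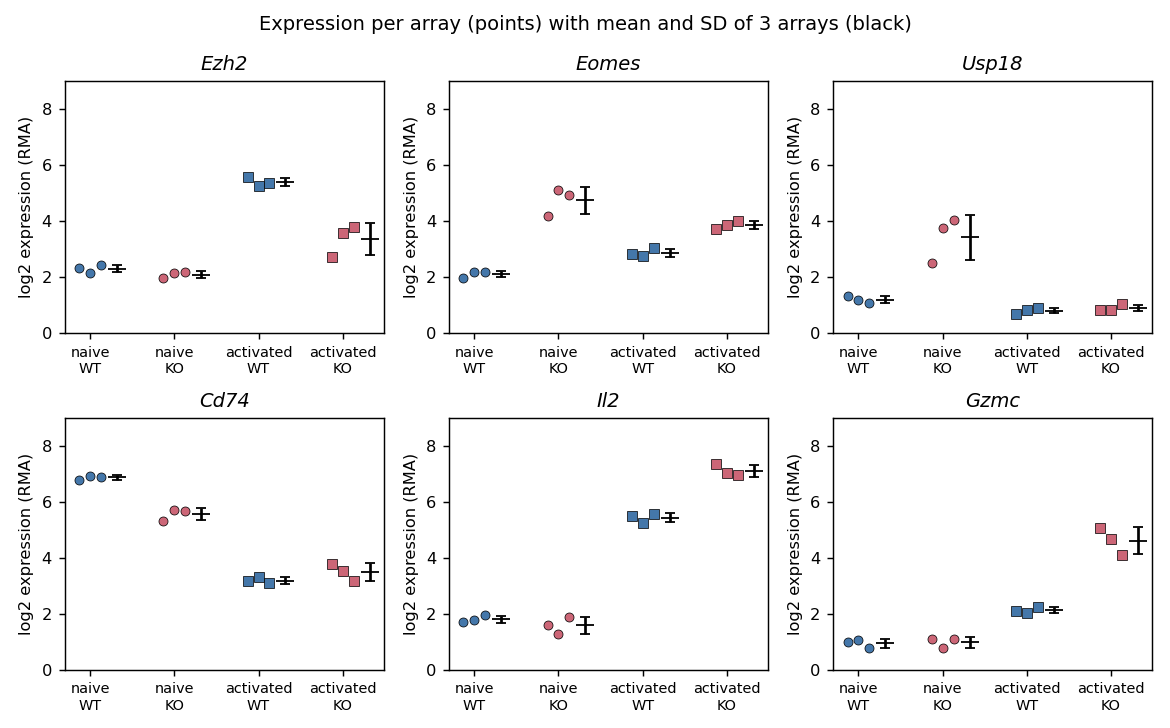
Log2 expression of 6 genes in each of the 12 arrays, with the mean and SD of each group of 3 in black. Ezh2 reads between 5.26 and 5.56 in activated wild-type cells and between 2.72 and 3.78 in activated knockout cells, while Eomes, Usp18 and Cd74 differ between genotypes in naive cells, and Il2 and Gzmc in activated cells.

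What is the normal response to activation? In wild-type cells 5612 of 20962 genes changed. The chemokine gene Ccl3 rose by 7.21 ± 0.13, the interleukin-2 receptor gene Il2ra by 5.86 ± 0.12, the granzyme gene Gzmb by 5.81 ± 0.12 and the interferon gene Ifng by 5.30 ± 0.27. Lta and Ccl4, which encode lymphotoxin and a chemokine, rose by 5.06 ± 0.11 and 5.02 ± 0.21. Among the largest falls were those of Fos (-5.76 ± 0.08), the quiescence regulator Klf2 (-4.51 ± 0.10), H2-Aa (-4.47 ± 0.24), H2-Ab1 (-4.40 ± 0.19), the egress receptor S1pr1 (-4.38 ± 0.21) and Dusp1 (-4.04 ± 0.11). H2-Aa and H2-Ab1 encode MHC class II, which mouse T cells do not make. Fos and Dusp1 belong to the early response and stress genes kept as a sign of handling, of which 10 rose and 12 fell of 22. Naive cells were freshly isolated and no array held cells cultured without stimulation. In either genotype, effects of stimulation, culture and handling therefore cannot be told apart.

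Genes of cell division and growth rose together in activated wild-type cells. Among mitosis genes 28 of 30 rose and 0 fell, among them Ube2c (4.11 ± 0.19) and Mki67 (3.13 ± 0.15), and 2 did not pass (camera adjusted p = 5.55e-26; limma is the test behind every such count, and over all genes 7475 had an unadjusted p under 0.05). Among genes of DNA replication 31 of 35 rose, such as Rrm2 (4.53 ± 0.11) and Mcm5 (2.96 ± 0.14), with 0 falls (4.66e-27). All 25 ribosome biogenesis genes rose, with Nolc1 (2.77 ± 0.11) and Mybbp1a (1.98 ± 0.10) among them (2.7e-22). Of 24 genes of amino acid transport and one-carbon metabolism 20 rose and 0 fell, among them Asns (4.53 ± 0.11), Slc7a5 (3.62 ± 0.11) and Shmt2 (3.53 ± 0.10) (2.7e-22). Glycolysis genes rose in 13 and fell in 1 of 17, with rises in Pgam1 (2.76 ± 0.13) and Pgk1 (2.16 ± 0.10) (1.07e-11). Cholesterol synthesis genes rose in 16 and fell in 0 of 22, with Idi1 (4.49 ± 0.16) and Cyp51 (2.66 ± 0.15) (5.62e-11). Adjusted over the list alone, the rises were 28, 32, 25, 22, 14 and 17 in the same order.

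T-cell genes went both ways in activated wild-type cells. Cytokine and chemokine genes rose in 17 and fell in 3 of 30 (camera adjusted p = 2.85e-10), with the same counts adjusted over the list alone. Naive and memory genes fell in 19 and rose in 1 of 24 (1.42e-17), among them the transcription factor Tcf7 (-1.66 ± 0.10) and Il7r (-2.47 ± 0.11). Genes of the T-cell receptor complex and proximal signalling, called receptor complex genes below, fell in 15 and rose in 4 of 23 (3.89e-06). Prkcq (-1.46 ± 0.12) was among those that fell. Cell-cycle inhibitors and p53 targets rose in 10 and fell in 4 of 22 (0.0114), with Cdkn1a up by 4.55 ± 0.21 and Ccng1 by 2.47 ± 0.18. Adjusted over the list alone, 19 naive and memory genes fell and 2 rose, 16 receptor genes fell and 4 rose, and 11 inhibitors and p53 targets rose and 5 fell. PRC2 genes rose in 7 and fell in 2 of 11 (0.00234), also over the list alone, with Eed up by 1.28 ± 0.18 and Suz12 by 0.73 ± 0.08; that list did not pass with an estimated correlation (adjusted p = 0.105 with an estimated correlation). The effector genes (14 rose and 9 fell of 31) and cytotoxic genes (6 rose and 5 fell of 18) did not pass as lists, with adjusted p = 0.0958 and 0.215. By limma 2 naive and memory genes rose without activated wild-type array 2, and 3 cytotoxic genes fell without naive wild-type array 3 or activated wild-type array 1.

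Of the markers of other cells, B-cell markers fell in 15 and rose in 0 of 20 (camera adjusted p = 5.5e-09, 15 also over the list alone), with Cd74 at -3.67 ± 0.14 and H2-Eb1 at -3.49 ± 0.12; by limma 1 rose without naive wild-type array 2. Monocyte, macrophage and neutrophil markers fell in 7 and rose in 0 of 24 (0.00152), such as Lyz2 (-1.19 ± 0.12), and that list did not pass with an estimated correlation (adjusted p = 0.0894 with an estimated correlation). The lists of plasma-cell (adjusted p = 0.833), dendritic-cell (0.536), erythroid and platelet (0.199) and stromal and endothelial markers (0.0541) did not pass. In all, 5612 genes passed in wild-type cells, 3109 higher and 2503 lower after activation, of which 1591 changed at least 2-fold.

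What is the response in cells with the Ezh2 knockout? In these cells 5595 genes changed upon activation. Ccl3 rose by 7.31 ± 0.13, Gzmb by 6.85 ± 0.12, Il3 by 6.46 ± 0.10, the chemokine gene Ccl9 by 5.81 ± 0.11, Il2ra by 5.67 ± 0.12 and the cholesterol synthesis gene Idi1 by 5.61 ± 0.16. Among the largest falls were those of Fos (-5.55 ± 0.08), Klf2 (-4.16 ± 0.10), Dusp1 (-4.14 ± 0.11), the migration receptor Gpr183 (-3.98 ± 0.17), Gzma (-3.91 ± 0.24) and Sidt1 (-3.73 ± 0.12). Of 5595 genes that passed, 3312 were higher and 2283 lower, and 1710 changed at least 2-fold. Among genes higher after activation in wild-type cells 2663 were also higher in knockout cells, against 491.2 under independence, and among lower genes 1480 were shared, against 272.6. Only 4 and 3 genes passed in opposite directions.

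In activated knockout cells 28 of 30 mitosis genes rose (camera adjusted p = 2.72e-27), with Ube2c at 4.32 ± 0.19 and Mki67 at 4.00 ± 0.15. Of the 35 DNA replication genes 32 rose (7.12e-25), of 25 ribosome biogenesis genes 23 (3.85e-18), of 24 amino acid and one-carbon genes 19 (3.66e-17), of 22 cholesterol genes 17 (1.03e-12) and of 17 glycolysis genes 14 (1.5e-11). In these 6 lists 1 glycolysis gene fell and no other gene did by limma, and the rises adjusted over the list alone were 29, 32, 24, 20, 18 and 15. Cytokine genes rose in 18 and fell in 2 of 30 (2.69e-13; 19 and 2 adjusted over the list alone), with Il2 up by 5.53 ± 0.14 and Ifng by 5.59 ± 0.27. Naive and memory genes fell in 19 and rose in 1 of 24 (6.45e-18; 20 and 1 adjusted over the list alone; 0 rose by limma without naive or activated knockout array 5, with 7261 genes at an unadjusted p under 0.05), and receptor complex genes fell in 18 and rose in 3 of 23 (5e-10; 19 and 4). Cell-cycle inhibitors and p53 targets rose in 12 and fell in 3 of 22 (0.00103; 13 and 3), with Cdkn1a at 4.11 ± 0.21 and Perp, a p53 target, at 3.15 ± 0.17. Effector genes rose in 14 and fell in 9 of 31 (0.00942; 14 and 10), among them Lgals3 (5.41 ± 0.11) and Cd44 (2.95 ± 0.15). That list had an adjusted p of 0.0571 when only genes above the median of all probe sets were tested, and its camera alternatives ranged from 0.00559 to 0.0571. Interferon-stimulated genes fell in 18 and rose in 5 of 29 (1.96e-05; 19 and 6 adjusted over the list alone), such as Usp18 (-2.53 ± 0.26) and Rtp4 (-2.18 ± 0.18). This did not pass with an estimated correlation (adjusted p = 0.182 with an estimated correlation). Upon activation of wild-type cells 13 of these 29 genes fell and 5 rose, also over the list alone, and the list did not pass (camera adjusted p = 0.196). In knockout cells B-cell markers fell in 10 and rose in 1 of 20 (1.5e-05, the same counts over the list alone), with Cd74 at -2.07 ± 0.14.

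How does Ezh2 loss change resting CD8 T cells? In naive cells 228 genes passed between genotypes, a few of them with large changes. Eomes, which encodes a T-box transcription factor of memory and effector CD8 T cells, was 6.19-fold higher in knockout cells (2.63 ± 0.18, adjusted p = 5.83e-07). Mela, a melanoma antigen gene related to retroviral envelope genes, rose by 4.84 ± 0.19 (4.04e-09), and all 3 of its probe sets passed. Klra8, which encodes a Ly49 receptor of natural killer (NK) cells, rose by 3.43 ± 0.27 (3e-06), and the chemokine receptor gene Cxcr3 by 1.64 ± 0.11 (5.36e-07). Itgae, which encodes the integrin CD103, fell by 2.66 ± 0.22 on the log2 scale (6.84e-06), and Tyrobp, which encodes a signalling adaptor of NK and myeloid cells, fell by 2.49 ± 0.15 (2.56e-07).

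Among the other genes with the largest changes in naive cells were Usp18 (2.23 ± 0.26), Klra18 (2.53 ± 0.44), Mid1 (2.36 ± 0.29), S100a6 (-2.28 ± 0.11) and S100a4 (-1.96 ± 0.08). The probe set of Mid1 carries the authors' antisense mark, so its call ended when such probe sets were left out. Without naive knockout array 4 the change of Klra18 was 3.34. The call of Klra18 ended when only the 6 arrays compared were fitted and with an intensity trend and robust variances. Of the genes that define a naive CD8 cell in the panel, Ccr7 (0.15 ± 0.09), Tcf7 (0.16 ± 0.10), Il7r (0.08 ± 0.11) and Cd8a (0.22 ± 0.09) did not pass, nor did Cd44 (0.54 ± 0.15, adjusted p = 0.145) or the cell-cycle inhibitor gene Cdkn2a (-0.04 ± 0.09).

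Interferon-stimulated genes rose in naive knockout cells, in 11 of 29 measured, and 0 fell; 18 did not pass, and 16 rose and 0 fell adjusted over the list alone (camera adjusted p = 8.07e-19, median change 0.56). Usp18, which restrains interferon signalling, led with 2.23 ± 0.26, followed by Ifit3 (1.18 ± 0.24), Rtp4 (1.17 ± 0.18) and the antiviral gene Oas1a (1.14 ± 0.15). The call of Ifit3 was lost without naive wild-type array 1, 2 or 3 or naive knockout array 5 or 6, with adjusted p up to 0.123. With limma 7 members passed without naive wild-type array 1, naive wild-type array 3 or naive knockout array 5, 14 passed without naive knockout array 4, and over all genes 1989 had an unadjusted p under 0.05. In the same arrays B-cell, plasma-cell and myeloid markers fell.

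Effector and memory-phenotype genes moved both ways in naive knockout cells, with 5 higher, 10 lower and 16 not passing of 31 (camera adjusted p = 0.000436 towards lower, median change -0.12; 6 higher and 12 lower adjusted over the list alone). Among the higher ones were Eomes, Cxcr3, Il2rb (0.56 ± 0.08) and Itgal (0.43 ± 0.09), and among the lower ones S100a6, S100a4, the chemokine gene Ccl5 (-0.99 ± 0.10) and Id2 (-0.95 ± 0.15). The call of Itgal was lost without naive wild-type array 1, 2 or 3 or naive knockout array 4 or 6, with adjusted p up to 0.0954. Eomes is also a member of the list of reported Ezh2 targets in T cells, in which it rose, Id2 fell and 15 of 17 did not pass (adjusted p = 0.448; 3 higher and 1 lower adjusted over the list alone). Of these targets 3 rose without naive knockout array 4 and 2 without array 6. Cytokine genes included Xcl1, higher by 1.22 ± 0.15, and Ccl5, lower, with 28 of 30 not passing (adjusted p = 0.816; 2 and 1 adjusted over the list alone); 3 rose without naive knockout array 4 and 2 without activated knockout array 6. Of 18 cytotoxic genes Gzmb fell by 0.71 ± 0.12 on the log2 scale and the other 17 did not pass (adjusted p = 0.299; 4 higher and 1 lower adjusted over the list alone), though 2 rose without naive knockout array 4 and 1 without activated knockout array 6. Of 24 naive and memory genes Igfbp4 (-1.94 ± 0.24) and Dapl1 (-1.38 ± 0.09) fell and Sidt1 (0.55 ± 0.12) rose (list adjusted p = 0.2; 4 lower and 1 higher adjusted over the list alone). The call of Sidt1 was lost without naive array 1, 2, 3, 4 or 6 or activated wild-type array 2 or 3, with adjusted p up to 0.16. Without naive knockout array 4, 5 members of that list fell.

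Of the markers of other cell types in naive knockout cells, B-cell markers fell in 6 and rose in 0 of 20 (camera adjusted p = 2.83e-12; 7 fell adjusted over the list alone), with H2-Ab1 at -1.54 ± 0.19, H2-Eb1 at -1.50 ± 0.12 and Cd74 at -1.30 ± 0.14, and with limma 3 passed without naive wild-type array 2. Myeloid markers fell in 4 of 24 (1.19e-07; 6 adjusted over the list alone), which were Lyz1 (-1.06 ± 0.12), S100a9 (-0.94 ± 0.15), Lyz2 (-0.73 ± 0.12) and S100a8 (-0.67 ± 0.11). The plasma-cell gene Jchain fell by 1.95 ± 0.13 on the log2 scale, the 1 member of 11 to pass both over all genes and over the list alone (list adjusted p = 1.9e-05). The dendritic-cell list fell as well (0.000823), with Irf8 (-1.03 ± 0.15) and Siglech (-0.46 ± 0.09) the 2 of 13 that passed, and 3 adjusted over the list alone. The call of Siglech was lost without naive wild-type array 2 or 3 or naive knockout array 4 or 5, which left 1, with adjusted p up to 0.119, and 1 other member rose without naive knockout array 4. NK-cell genes went both ways, with 1 of 19 higher (Klra8) and 3 lower, Tyrobp among them, and the list did not pass (0.337). Adjusted over the list alone, 1 NK-cell gene was higher and 4 were lower. Erythroid and platelet (0.928), stromal and endothelial (0.086), and CD4 and regulatory T-cell markers (0.23) did not pass as lists. However, 3 probe sets shared by haemoglobin genes, which enter no list because they belong to several genes, were lower in naive knockout cells (-1.94 to -1.46).

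Polycomb genes themselves did not pass in naive cells. No member of the PRC2 list (11 genes, list adjusted p = 0.322), of the PRC1 list (18 genes, 0.2) or of the 70 developmental regulators bound by Polycomb in many cell types (0.884) passed, by limma or adjusted over the list alone, and Ezh1 was at 0.14 ± 0.11. The same was true of mitosis genes (30 genes, 0.299), ribosomal proteins (24 genes, 0.811) and early response genes (22 genes, 0.884), except that 1 mitosis gene fell without naive knockout array 6 and 1 early response gene rose without array 4. Genes of the T-cell receptor complex and proximal signalling passed towards higher (camera adjusted p = 0.00514). That call did not hold with an estimated correlation (adjusted p = 0.178 with an estimated correlation). Txk alone of these genes passed, at 0.55 ± 0.09, and 3 adjusted over the list alone. By limma 2 passed without naive knockout array 4 or activated knockout array 6. In all, 228 genes passed in naive cells, 130 higher and 98 lower in the knockout, and 61 changed at least 2-fold. Without naive wild-type array 1 the count was 139, and without naive wild-type array 3 it was 148. The lists of interferon-stimulated, effector, B-cell, plasma-cell, myeloid and dendritic-cell genes passed with an estimated correlation, with adjusted p = 0.0247, 0.0198, 0.0143, 0.0175, 0.0247 and 0.031.

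How does Ezh2 loss change stimulated CD8 T cells? In activated cells 277 genes passed between genotypes, 9 cytokine and chemokine genes of 30 among them. Perp rose by 2.61 ± 0.17 (adjusted p = 1.07e-06), Inhba, which encodes a subunit of activin, by 2.48 ± 0.12 (3.19e-08), the granzyme gene Gzmc by 2.48 ± 0.18 (4.01e-06), and the cytokine gene Il9 by 2.44 ± 0.20 (6.13e-06). Mela rose by 4.17 ± 0.19 (3.19e-08), with all 3 probe sets passing, while for Inhba 1 of 2 probe sets passed, and Idi2, an isomerase gene, by 2.22 ± 0.18 (6.13e-06). Il2 was 3.19-fold higher (1.68 ± 0.14, 1.04e-05). Among probe sets of 1 gene, besides Ezh2 and transcripts without a gene name, the largest falls were in Slc35g1 (-0.97 ± 0.14) and the adhesion molecule gene Cd2 (-0.96 ± 0.08). Next came the inhibitory receptor gene Ctla4 (-0.96 ± 0.12), Igkv8-30 (-0.93 ± 0.10) and Dapl1 (-0.91 ± 0.09).

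Cytokine and chemokine genes rose in 9 and fell in 0 of 30, and 21 did not pass (camera adjusted p = 3.56e-14, median change 0.25; 12 rose and 1 fell adjusted over the list alone). With Il9 and Il2, Il3 (2.09 ± 0.10) and Ccl1 (1.57 ± 0.12) led the list, while Ifng (0.37 ± 0.27, adjusted p = 0.81) and Tnf (0.58 ± 0.15, 0.099) did not pass. Of 18 cytotoxic genes 4 rose and 0 fell (5.76e-06; 6 and 0 adjusted over the list alone): Gzmc, the perforin gene Prf1 (1.12 ± 0.18), the granzyme inhibitor gene Serpinb9 (0.97 ± 0.11) and Serpinb6b (0.81 ± 0.16). The call of Serpinb6b was lost without activated wild-type array 1, 2 or 3 or activated knockout array 4, with adjusted p up to 0.0887. Gzmb did not pass (0.33 ± 0.12, 0.275). Without activated knockout array 5, 1 cytokine gene fell. Over all genes 2119 had an unadjusted p under 0.05 by limma.

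Effector and memory-phenotype genes rose in 8 and fell in 0 of 31 in activated knockout cells (camera adjusted p = 0.00665, median change 0.08; 12 rose and 6 fell adjusted over the list alone). Lgals3 (1.23 ± 0.11), Eomes (1.01 ± 0.18) and Cd44 (0.94 ± 0.15) were the largest of these. By limma 4 members passed without activated wild-type array 2 and 5 without activated knockout array 6, and with the mean over the probe sets of each gene the list had an adjusted p of 0.069, the highest of its camera alternatives, which began at 0.00318. Of the reported Ezh2 targets Eomes, the pro-apoptotic gene Bcl2l11 (0.84 ± 0.18) and Id2 (0.68 ± 0.15) passed among 17 (0.0304; 4 rose and 1 fell adjusted over the list alone), which did not hold with an estimated correlation (adjusted p = 0.236 with an estimated correlation). With activated wild-type array 2 or 3 left out, Eomes alone of them passed, and Bcl2l11 did not pass without activated wild-type array 1 or activated knockout array 4 or 5, nor Id2 without naive wild-type array 1, 2 or 3 or activated knockout array 5 or 6. The list call was lost without activated wild-type array 2 or activated knockout array 4 or 5 (0.136, 0.0517 and 0.14), and its camera alternatives ranged from 0.00369 to 0.236. Of 24 naive and memory genes Il7r (0.73 ± 0.11) and Actn1 (0.68 ± 0.09) rose, and Dapl1 and Bcl2 (-0.37 ± 0.08) fell, and the list did not pass (0.894; 6 rose and 5 fell adjusted over the list alone). The call of Bcl2 was lost without activated wild-type array 1, 2 or 3 or activated knockout array 5 or 6, which left 1 fall, with adjusted p up to 0.123.

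Genes of the T-cell receptor complex and proximal signalling fell in 5 and rose in 0 of 23 (camera adjusted p = 0.000108). Adjusted over the list alone, 8 fell and 2 rose. The list call did not hold with an estimated correlation (adjusted p = 0.0553 with an estimated correlation). The 5 genes were Cd2, Cd8b1 (-0.54 ± 0.10), Lck (-0.49 ± 0.11), Cd3d (-0.47 ± 0.10) and Cd8a (-0.45 ± 0.09). By limma 1 passed without activated wild-type array 1 or 3, and 3 passed without activated knockout array 4, 5 or 6; Cd8a was also lost without activated wild-type array 2, with adjusted p = 0.104. Of 24 amino acid and one-carbon genes Atf5 (-0.76 ± 0.12) and Trib3 (-0.65 ± 0.11), both stress-response regulators, fell (6.81e-06; 2 also over the list alone). The CD4 and regulatory T-cell list fell (0.000737; 3 of 12 fell adjusted over the list alone), with Ctla4 and Izumo1r (-0.72 ± 0.16). The call of Izumo1r was lost without any of the 3 activated wild-type arrays, naive wild-type array 1, naive knockout array 5 or activated knockout array 4 or 6, which left 1, with adjusted p up to 0.132. Interferon-stimulated genes fell in 3 and rose in 0 of 29 (0.00665; 4 fell adjusted over the list alone), among them Iigp1 at -0.86 ± 0.13 and Irgm1 at -0.49 ± 0.09. This did not hold with an estimated correlation (adjusted p = 0.412 with an estimated correlation). By limma 1 of the 3 passed without activated wild-type array 1 or 2 or activated knockout array 5, where Irgm1 had an adjusted p up to 0.082. B-cell markers did not pass as a list in activated cells (0.814), with 1 of 20 lower and 0 higher by limma. The lower one was Ighm (-0.445 ± 0.097, adjusted p = 0.0349). Its call was lost without naive array 2 or 6 or activated array 1, 2, 3, 4 or 5. By limma 1 member rose without naive array 2, 3 or 4. Adjusted over the list alone, 1 rose and 2 fell. Outside the list, 3 probe sets shared by immunoglobulin genes were lower in activated knockout cells (-1.49 to -1.36).

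Of mitosis genes 1 of 30 rose (Cenpa, 0.66 ± 0.13), and 3 adjusted over the list alone; the list passed (camera adjusted p = 0.0016) but not with an estimated correlation (adjusted p = 0.233 with an estimated correlation) nor without activated knockout array 6 (0.102), with camera alternatives from 5.78e-05 to 0.233. The call of Cenpa was lost without activated wild-type array 2 or 3 or activated knockout array 4 or 5, with adjusted p up to 0.109, which left 0 by limma but 2 without activated knockout array 4. Mki67 (0.32 ± 0.15, adjusted p = 0.503), Myc (0.16 ± 0.08, 0.603), Cdkn2a (0.02 ± 0.09, 0.993) and Tbx21 (-0.24 ± 0.09, 0.342) did not pass, and 0 of 70 developmental regulators bound by Polycomb passed by limma or adjusted over the list alone (0.634). In all, 277 genes passed in activated cells, 199 higher and 78 lower in the knockout, which makes 71.8% higher. Of them 49 changed at least 2-fold. The count was 182 without activated wild-type array 1, 147 without array 2 and 150 without array 3. It was 153 when only the 6 arrays compared were fitted. The lists of cytokine, cytotoxic, effector, amino acid, and CD4 and regulatory genes passed with an estimated correlation, with adjusted p = 0.00448, 0.0319, 0.0476, 0.0319 and 0.0319.

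**Figure D2:**
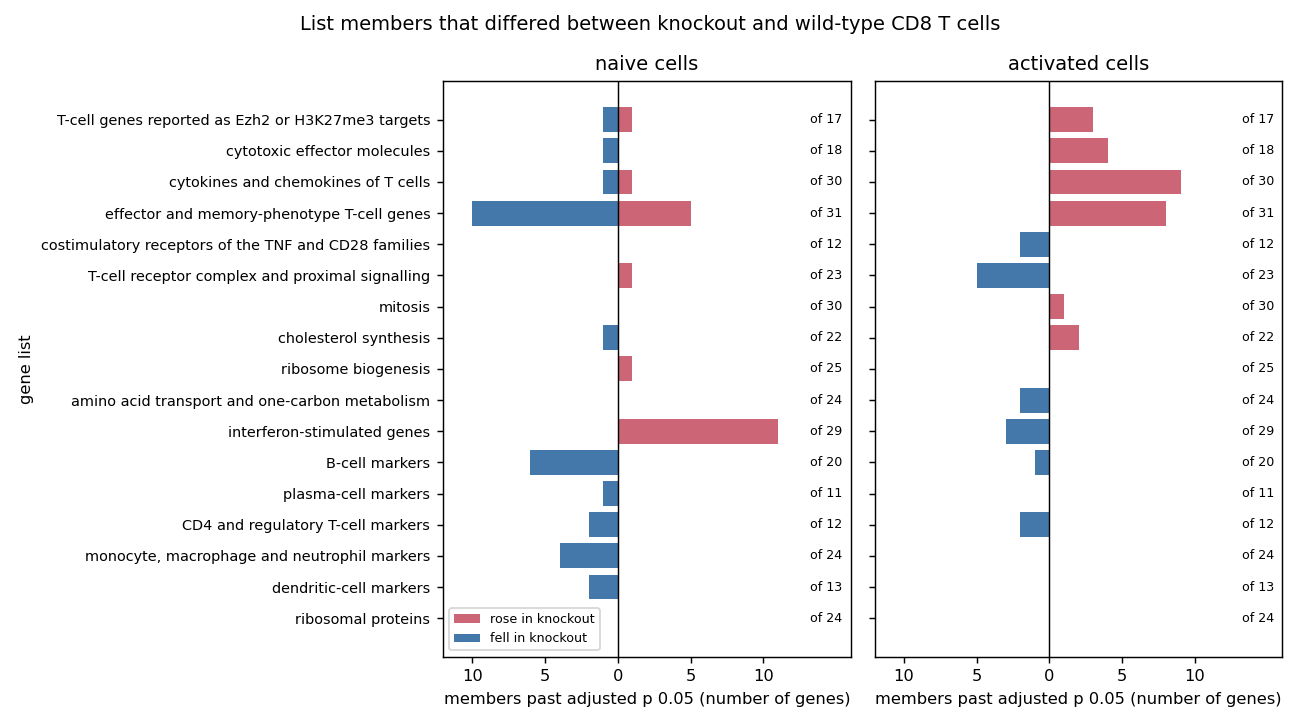
Number of members of each gene list that rose (right) or fell (left) in knockout against wild-type cells, in naive and activated cells, for the 17 lists that passed in at least 1 of the states with the preset correlation; the number measured stands at the right. Interferon-stimulated genes rose in naive cells (11 of 29), and cytokine genes in activated cells (9 of 30).

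The interaction asks whether the genotypes respond differently to activation, which is the same as asking whether the knockout acts differently in the 2 states. A higher response there can be a larger rise or a smaller fall. Il2 rose more in knockout cells, by 1.90 ± 0.20 (adjusted p = 0.000138), as did Inhba (2.67 ± 0.17), Perp (2.66 ± 0.24), the vasodilator peptide gene Adm (2.59 ± 0.29), Gzmc (2.44 ± 0.26) and Gzmb (1.04 ± 0.17). Gzmb started lower in naive knockout cells, at 1.33 against 2.04. Eomes rose upon activation in wild-type cells by 0.75 ± 0.18 and fell in knockout cells by -0.87 ± 0.18, so its interaction was -1.62 ± 0.25 (0.00381). Klra8 (-3.46 ± 0.38), Usp18 (-2.14 ± 0.37), Cxcr3 (-1.15 ± 0.15), Ly6a (-1.44 ± 0.21) and Il2rb (-0.82 ± 0.11) also responded lower in knockout cells. Tyrobp (2.52 ± 0.21) and Itgae (2.43 ± 0.31) had higher interaction values, since both fell upon activation in the wild type and were already low in naive knockout cells.

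Cytokine genes had a higher response in knockout cells in 9 and a lower one in 0 of 30 (camera adjusted p = 3.74e-09; 10 and 1 adjusted over the list alone), such as Il9 (2.34 ± 0.28) and Il3 (1.91 ± 0.15), and 2 had a lower one without naive knockout array 4. Effector genes had a higher response in 10 and a lower one in 4 of 31 (8.11e-06, and 14 and 4 adjusted over the list alone), led by Lgals3 (2.07 ± 0.16), S100a6 (2.03 ± 0.16), S100a4 (1.69 ± 0.12) and Ccl5 (1.67 ± 0.15). S100a6 and S100a4 were lower in naive knockout cells and did not pass between genotypes in activated ones. Lgals3 and Ccl5 were lower in naive and higher in activated knockout cells. Interferon-stimulated genes had a lower response in 8 and a higher one in 0 of 29 (5.27e-19; 16 and 0 adjusted over the list alone), among them Usp18, Iigp1 (-1.31 ± 0.19) and Irf7 (-1.06 ± 0.17). By limma 4 of them passed without naive wild-type array 1 or activated wild-type array 2, 5 without activated wild-type array 1, and 13 without naive knockout array 4. Receptor complex genes had a lower response in 4 of 23 (5.62e-07; 6 adjusted over the list alone), among them Cd2 (-1.15 ± 0.12) and Lck (-0.93 ± 0.15). Of these receptor genes 2 passed without naive wild-type array 2 or 3, activated wild-type array 1 or 2 or naive knockout array 5 or 6, and 1 had a higher response without naive knockout array 4. B-cell markers had a higher value in 3 of 20 (4.96e-07; 5 adjusted over the list alone), which were Cd74 (1.60 ± 0.20), H2-Ab1 (1.49 ± 0.27) and H2-Eb1 (1.36 ± 0.17). In all, 182 genes passed, 127 with a higher and 55 with a lower response in knockout cells, and over all genes 2057 had an unadjusted p under 0.05. With an estimated correlation the cytokine, effector, interferon, receptor complex and B-cell lists had adjusted p = 0.0108, 0.0108, 0.024, 0.024 and 0.024.

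Ribosomal proteins, kept as a sign of RNA quality, fell upon activation of knockout cells in 9 of 24 and rose in 0 (camera adjusted p = 0.0014; 9 also over the list alone), among them Rpl5 (-0.82 ± 0.13) and Rps14 (-0.74 ± 0.12). This did not hold with an estimated correlation (adjusted p = 0.185 with an estimated correlation), and 5 passed without activated knockout array 6. In wild-type cells the list did not pass upon activation (0.0685). Between genotypes in activated cells the list passed towards lower (0.0263), although 0 members passed by limma or adjusted over the list alone, with Rps19 at -0.39 ± 0.11 and Rps14 at -0.36 ± 0.12. That did not hold with an estimated correlation (adjusted p = 0.395 with an estimated correlation) nor without activated wild-type array 3 (0.122) or activated knockout array 6 (0.0607). Of 22 early response and stress genes, kept as a sign of handling, 3 rose and 0 fell between genotypes in activated cells (4 rose and 2 fell adjusted over the list alone), and the list did not pass (0.0952). They were Hspa1b (1.01 ± 0.20) and Ier3 (0.80 ± 0.15), both with antisense-marked probe sets, and Atf3 (0.71 ± 0.14). Without activated wild-type array 2 none of the list passed, and 1 passed without activated wild-type array 3 or activated knockout array 4. Hspa1b and Ier3 were also lost without activated wild-type array 1, Ier3 without activated knockout array 5 and Atf3 without array 6, with adjusted p up to 0.104. Over all genes 7261 in activation of knockout cells and 2119 between genotypes in activated cells had an unadjusted p under 0.05.

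Some further lists passed with the preset correlation. In the interaction the cholesterol synthesis list passed towards higher (camera adjusted p = 7.33e-05, and 0.0455 with an estimated correlation), with Hmgcs1 at 0.97 ± 0.12, and the amino acid list towards lower (7.33e-05 and 0.0289). The others did not pass with an estimated correlation, whose adjusted p stands second here. Upon activation of wild-type cells these were BCL2 family genes and death receptors (0.0194 and 0.114) and inhibitory receptors with exhaustion-associated genes (0.0205 and 0.0657). Both lists went towards higher. Among their rising members were Birc5 (2.73 ± 0.09), which is also in the mitosis list, and Cd200 (3.01 ± 0.18). In knockout cells they were the same lists (0.0155 and 0.137, 0.0463 and 0.107) and PRC2 genes (0.0416 and 0.224). Between genotypes in naive cells they were cholesterol synthesis towards lower (0.039 and 0.288) and ribosome biogenesis towards higher (0.00267 and 0.378). In activated cells they were costimulatory receptors towards lower (0.0118 and 0.0615) and cholesterol synthesis towards higher (0.0004 and 0.0615). In the interaction they were PRC2 (0.0431 and 0.224) and ribosome biogenesis (0.000695 and 0.224) towards lower. The PRC2 list holds the targeted gene Ezh2 itself, whose interaction was -1.82, against a mean of -0.25 over its 11 genes. That call therefore partly restates the knockout. Cytotoxic (0.0102 and 0.149), mitosis (0.000932 and 0.175), myeloid (6.66e-05 and 0.0536) and dendritic-cell genes (0.0431 and 0.149) passed in the interaction towards higher.

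Leaving out 1 array ended several of these calls. In wild-type activation the BCL2 list was lost without naive wild-type array 3 (0.0567). In knockout activation inhibitory receptors were lost without naive wild-type array 3 (0.0508), naive knockout array 5 (0.0658) or activated knockout array 4 (0.0544) or 5 (0.0605), and with a replicate block (0.0611). PRC2 genes were lost there without activated wild-type array 3 (0.0523), naive knockout array 6 (0.058) or activated knockout array 5 (0.0523). Between genotypes in naive cells cholesterol synthesis was lost without naive wild-type array 1 (0.0602) or 2 (0.153), naive knockout array 4 (0.0933) or activated knockout array 4 (0.0624), and ribosome biogenesis without naive wild-type array 3 (0.162) or naive knockout array 5 (0.129). In the interaction cytotoxic genes were lost without naive knockout array 4 (0.0689). PRC2 genes were lost there without naive wild-type array 1 (0.0569) or 3 (0.168), activated wild-type array 1 (0.117), naive knockout array 4 (0.055) or 5 (0.094) or activated knockout array 5 (0.0505). Dendritic-cell genes were lost without naive wild-type array 2 (0.0528) or 3 (0.0647), activated wild-type array 2 (0.069), naive knockout array 4 (0.202) or 5 (0.0545) or activated knockout array 4 (0.074) or 5 (0.0573).

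Genes that passed between genotypes in naive and in activated cells overlapped. Of 130 genes higher in naive knockout cells 23 were also higher in activated ones, against 1.2 under independence, and of 98 lower genes 7 were lower in both, against 0.4. A further 10 genes were lower in naive and higher in activated knockout cells, against 0.9, and 0 went the other way by limma, against 0.5. Both states came from the same mice and shared 1 estimate of the spread per gene. More overlap than under independence can arise from that alone, so those values are only a reference.

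**Figure D3:**
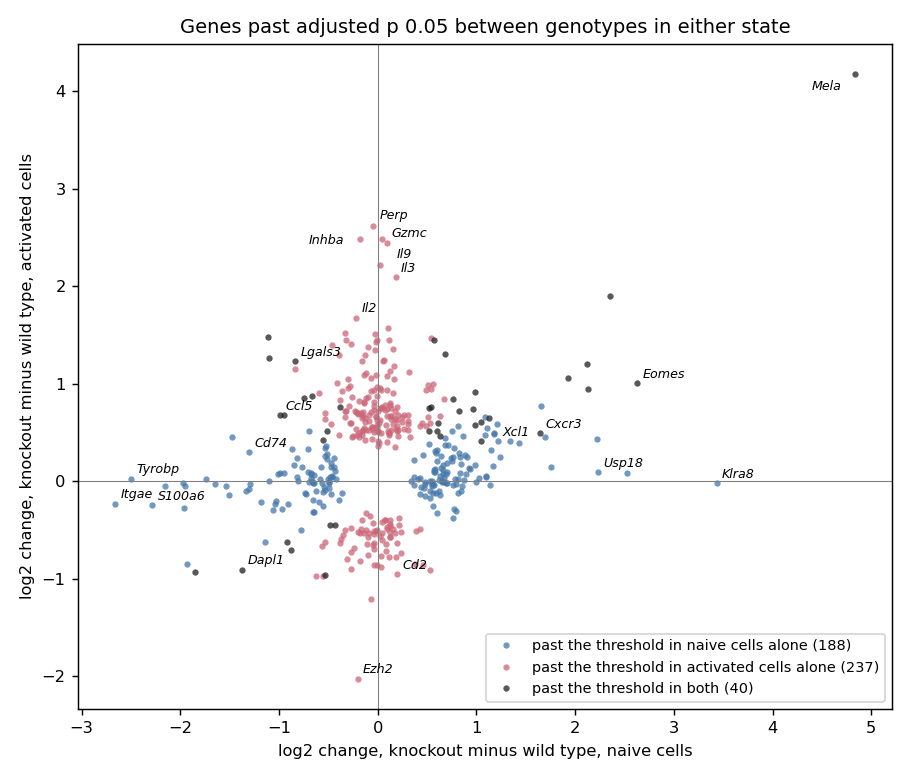
Log2 change between knockout and wild-type cells in naive cells (horizontal) and in activated cells (vertical) for every gene that passed in either state, each point 1 gene. Mela is the highest in both states, 188 genes passed in naive cells alone, 237 in activated cells alone and 40 in both.

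The authors' deposited selection, made on probe sets at an unadjusted p under 0.01 and a ratio over 1.3, holds 7244 and 7816 probe sets for activation of wild-type and knockout cells. It holds 630 for the genotypes in naive cells (366 higher and 264 lower in the knockout), 661 in activated cells (434 and 227), and 797 for the interaction. The deposited ratios and the differences between group means computed here had Pearson's r = 1.0000 across probe sets, which are not independent replicates, with a largest difference of 4.4e-08 on the log2 scale.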

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

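Chosen only after the result was seen were the tests of the B-cell markers, of single interferon-exposed mice, of dendritic cells and of other splits of the arrays, and the reading of the markers of other cell types; the test of the genes near Ezh2 and the bound for those markers were written before.

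B-cell, plasma-cell and myeloid transcripts were lower in naive knockout cells, with Cd74 at 5.56 against 6.86 in the wild type, although cells were purified to above 93% CD8. Fewer B cells among the naive knockout cells may be the source, but the test of it, that the 6 list members lost in culture had every naive knockout array below every naive wild-type array (100%), ran on the same 6 genes that passed here, so it restates the pattern and the explanation stays open. A low share of all other cell types would lower erythroid, platelet, stromal and endothelial markers too, and their mean change was -0.04 (SE 0.03, 29 markers), which met the bound written against that explanation. Only 1 of these markers lay at least 1 log2 unit above the median probe set (0.97), and 3 probe sets shared by haemoglobin genes were lower (-1.94 to -1.46), so that bound was not informative and the explanation stays open. Litter, cage and day of isolation are not in the labels, so they stay open and untested, as does an effect of Ezh2 loss itself.

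Interferon-stimulated genes were higher in naive knockout cells, 11 of 29 by limma. If 1 knockout mouse with strong interferon exposure were the source, few would pass without it, but the fewest when 1 naive knockout array was left out was 7, which argues against that. More plasmacytoid or other dendritic cells would raise the dendritic-cell list, whose mean change was -0.20 (SE 0.09, 13 genes, which are not independent replicates). The fall of this list was already known when the bound was written, so the bound does not test that explanation. The values show only that these markers as a list were lower, not higher. An infection or exposure shared by the 3 knockout mice was not tested, since the labels give no cage or litter, and it stays open beside an effect of Ezh2 loss.

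Mela differed between genotypes in both states (4.84 and 4.17) and Klra8 in naive cells (3.43) and did not pass in activated ones, where it read 0.72 in the knockout and 0.75 in the wild type. This may reflect a stretch of another strain's chromosome carried along with the targeted Ezh2 gene. Of the 200 tested genes nearest Ezh2 3 (1.5%) passed between genotypes in either state, against 438 of 18189 other placed genes (2.41%), a ratio of 0.62 (one-sided Fisher exact p = 0.862), which argues against a stretch rich in changed genes around Ezh2. Klra8 lies on chromosome 6, as Ezh2 does, but is not among the 200 genes nearest Ezh2, and Mela and Klra18 could not be placed. The test of that stretch therefore does not cover Mela, Klra8 or Klra18 themselves. Strain differences elsewhere in the genome and an effect of Ezh2 loss on these genes stay open.

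The activation response differed between genotypes in 182 genes, of which 51 are named here as log2 differences. A higher response means a higher log2 change, so a smaller fall from a lower naive value counts as well as a larger rise. In wild-type cells H2-Ab1 read 5.71 when naive and 1.314 when activated. In knockout cells H2-Ab1 read 4.175 when naive and 1.29, 1.07 and 1.45 in activated arrays 4, 5 and 6. Higher responses in knockout cells that passed without any 1 array were those of Inhba 2.67, Perp 2.66, Adm 2.59, Tyrobp 2.52, Gzmc 2.44, Itgae 2.43, Il9 2.34, Lgals3 2.07, S100a6 2.03, Il3 1.91, Il2 1.90, Jchain 1.89, S100a4 1.69, Ccl5 1.67, Id2 1.63, Cd74 1.60, H2-Ab1 1.49, H2-Eb1 1.36, Gzmb 1.04, Hmgcs1 0.97, Serpinb9 0.97, Gadd45a 0.87 and Actn1 0.77. Lower ones were those of Klra8 -3.46, Usp18 -2.14, Ezh2 -1.82, Eomes -1.62, 5830411N06Rik -1.61, Ly6a -1.44, Iigp1 -1.31, Cd2 -1.15, Cxcr3 -1.15, Irf7 -1.06, Lck -0.93 and Il2rb -0.82. For 16 genes the call was lost without at least 1 array, with the highest adjusted p so reached in brackets: Hspa1b 1.43 (0.0837), Idi1 1.11 (0.0872), Fdft1 1.04 (0.135), S100a9 1.03 (0.112), Cenpa 0.99 (0.0611), Atf3 0.93 (0.105), Cd160 0.83 (0.066), Lyz1 0.77 (0.121), Lyst -1.79 (0.0557), Oas1a -1.18 (0.0554), Icos -0.90 (0.0584), Psat1 -0.72 (0.13), Cd8a -0.67 (0.0657), Bcl2 -0.59 (0.0626), Txk -0.58 (0.125) and Itgal -0.56 (0.126). Of these, 11, 12 and 11 were lost without naive wild-type arrays 1, 2 and 3, 10, 12 and 13 without activated wild-type arrays 1, 2 and 3, 6, 12 and 10 without naive knockout arrays 4, 5 and 6, and 9, 7 and 3 without activated knockout arrays 4, 5 and 6. With a replicate block for the mouse the calls of Atf3 (adjusted p = 0.0864), Itgal (0.0829), Fdft1 (0.0825), Cd8a (0.0749), Txk (0.0617), Psat1 (0.0595), Lyz1 (0.0568) and S100a9 (0.0507) were lost as well.

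Probe sets with no gene or several genes were tested apart, and of 6493 tested 30 were higher and 35 lower in naive knockout cells, and 4 were higher and 17 lower in activated ones.

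With 3 arrays against 3 there are 10 splits, too few for a share under 0.05; 1 split in each comparison, the real one, gave as many genes. The real counts were 5612, 5595, 228, 277 and 182 for activation of wild-type and of knockout cells, the genotypes in naive and in activated cells, and the interaction, and the highest counts of the other splits were 0, 0, 1, 0 and 0 by limma, with 7475, 7261, 1989, 2119 and 2057 genes at an unadjusted p under 0.05 in the real ones.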

How the results depend on the processing

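The array-weight, threshold and other settings were planned, except that leaving out antisense-marked probe sets and the term for arrays numbered 9 to 12 were chosen only after the data were seen. With at least a 2-fold change, a stricter threshold by construction, 1591 and 1710 genes passed upon activation of wild-type and knockout cells, 61 and 49 between genotypes in naive and activated cells, and 96 in the interaction. An adjusted p under 0.01 left 113, 115 and 92 for the last 3 of these and the unmoderated model 56, 71 and 52. Array weights gave 379 genes in naive cells and 282 in the interaction, and fitting only the arrays compared gave 153 in activated cells; the cause was not tested. Without 1 array the counts ranged from 4639 to 5924 and 4963 to 5557 for activation, from 139 to 290 in naive cells (139 without naive wild-type array 1, 148 without array 3), from 147 to 316 in activated cells (182, 147 and 150 without activated wild-type arrays 1, 2 and 3) and from 122 to 234 for the interaction. Fewer arrays lower a count, but why counts rose without some of the knockout arrays was not tested; estimated array weights ran from 0.491 to 1.622 and were lowest for activated knockout arrays 6 (0.491) and 4 (0.592) and naive knockout array 4 (0.626). With a replicate block for the mouse the counts were 5534, 5565, 230, 272 and 179. Ezh2 in activated cells ranged from -2.23 to -1.7 without 1 array. Of 31 lists, fry called 27 and 28 upon activation, and an estimated correlation left 5 in activated cells and 7 in the interaction; without 1 array, 14 to 17, 15 to 17, 8 to 10, 11 to 13 and 11 to 15 lists passed in the 5 comparisons. Of 475 passing results for named genes 256 passed in every setting and 0 reversed, and with the replicate block 15 were lost and 1 was gained (Mki67 in the interaction, adjusted p from 0.0787 to 0.0211). The series table and the workbook hold the same values to 5.0e-09, so that alternative was not run, and no detection calls were at hand for values near the floor.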

Other observations

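The genes named in this part and the tests of probe-set classes were chosen only after the values were seen.

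Among the 40 genes past the threshold between genotypes in naive and in activated cells, 11 passed in both states without any 1 array. Mela (4.84 ± 0.19 in naive and 4.17 ± 0.19 in activated cells), Eomes (2.63 ± 0.18 and 1.01 ± 0.18), Mid1 (2.36 ± 0.29 and 1.90 ± 0.29), Arsb (2.13 ± 0.14 and 0.94 ± 0.14), Rnf157 (2.12 ± 0.16 and 1.20 ± 0.16), Itm2a (1.93 ± 0.18 and 1.06 ± 0.18) and the kinase gene Sgk1 (0.68 ± 0.11 and 1.31 ± 0.11) were higher in knockout cells in both, and the probe set of Mid1 carries the antisense mark. Dapl1 (-1.38 ± 0.09 and -0.91 ± 0.09) and Igkv8-30 (-1.85 ± 0.10 and -0.93 ± 0.10) were lower in both. Ccl5 (-0.99 ± 0.10 and 0.68 ± 0.10) and Lgals3 (-0.84 ± 0.11 and 1.23 ± 0.11) were lower in naive and higher in activated knockout cells, and their interactions passed (1.67 ± 0.15 and 2.07 ± 0.16).

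Among probe sets with no gene or several genes, 13 of immunoglobulin genes were lower in naive knockout cells (-3.70 to -0.78) and 3 in activated ones (-1.49 to -1.36). A probe set shared by Klra genes was higher in naive knockout cells (3.79), as was a probe set of Ly6c genes (0.84).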
